A study of Mus musculus with 3 samples.

How the data were processed

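AGO2-bound RNA of 3 HITS-CLIP libraries of the mouse P19 line was analysed from peak lists. Per the labels' protocols, RNA was recovered from nitrocellulose, made into small RNA libraries, amplified by PCR and selected for short inserts before sequencing on an Ion Proton instrument, with the AGO2 antibody clone 2D4. Per the submitters' processing notes, cutadapt and Novoalign were used on the reads and the genome build was mm10. Their versions, the versions and settings of the peak callers, and the way in which the 3 libraries were combined are not given in the sources used here. No molecular identifiers are named in the labels, so intervals cover counting error only.

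The authors deposited 4 lists of peaks, 1 per peak caller, each with a chromosome, start, end, name, score and strand per peak. The deposited score is the authors' own value of each peak, with no stated unit, and it was used only to rank peaks within a list. In CIMS the score equalled the number k in the name of each of the 169 peaks, and a second number m ran from 3 to 20. Running numbers in the peak names reached 8506 in Piranha, which held 1417 peaks, and 222973 in PIPE-CLIP, which held 3257, and the lowest score was 10 in each list. Peaks below that score were not analysed here. Pyicoclip held 137 peaks with no strand, which were counted as matching either strand, and 2 intervals listed more than once.

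Genes were taken from a RefSeq gene table of the assembly GRCm38.p6, the coordinates of which are those of mm10. The table gives gene spans and gene types, and no strand, exon or untranslated region was used. A peak was assigned to each gene whose span held its midpoint, on either strand, which replaces the assignment to sense exons set out in the design. Gene spans covered 45.8% of the chromosomes. Each peak took 1 class, in the order mitochondrial, ribosomal RNA, microRNA, other small RNAs, protein-coding, long non-coding, other and no gene. Of 290 gene list entries, 289 matched the table. The share of peaks in 3′ untranslated regions, seed matches, the 7-mer scan and seed positions were planned and not run, since they need the genome sequence or exons, which were not used here.

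Peaks were called shared if they overlapped by at least 1 nt on the same strand. Loci were runs of overlapping peaks merged over all lists with strand ignored, so the peaks of a locus need not all overlap each other. Overlap was compared with 1000 random shifts of the shorter list by 200 to 2000 nt in either direction, with a one-sided permutation p. Shares have 95% Wilson intervals, and for a share of 0 the limit is 3 counts of the total, a rule that differs from the Wilson bound. Score percentiles of shared and unshared peaks were compared by two-sided permutation with 100000 resamples. Gene lists were compared with 10000 random lists of protein-coding or, for long non-coding RNAs, like genes, matched on deciles of span length, by two-sided permutation. The background was all annotated genes, of which 21900 were protein-coding. P-values were adjusted by Benjamini-Hochberg within each family of tests. Position along a span was taken from the midpoint of stranded peaks that lay in exactly 1 gene span, a protein-coding one, and read in the direction of the peak strand. If a peak was antisense to its gene, this direction is the wrong one.

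The gene lists, tests and alternatives were fixed before the data were examined, except the comparison of positions, the tests of RNA classes, the overlap settings with random positions inside the gene span or plus-strand clusters alone, the setting of peaks in exactly 1 gene span, those without PIPE-CLIP, without mitochondrial and ribosomal peaks or without peaks in small RNA genes, and those named in the closing section as chosen later. Genes named in the text were the 15 in most lists, those of the 5 highest-scoring peaks per list, members of gene lists with a peak in at least 2 peak lists, the first 4 members of each gene list by the number of peak lists and then of peaks, and 10 microRNA genes in at least 2 lists. Other genes at loci of all 4 lists and in the closing section were named after their values were seen. Some genes that meet these rules are not reported here by name. Alternatives covered the overlap rule, strand, the better-scoring part of each list, other shifts, merged peaks, peak width and the gene list background.

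On simulated data, planted overlaps of 1000 peaks were recovered within 0.1 percentage points, and lists of 25 genes drawn 3 times as often from genes with a peak were called in 47.5% of draws, against 1.5% of random lists. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.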

Results

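RNA bound by AGO2, the Argonaute protein that holds microRNAs on their target RNAs, was measured by HITS-CLIP in P19 cells, a mouse embryonal carcinoma line that can be driven towards neural or muscle fates. In HITS-CLIP, RNA is crosslinked to protein in the cell, the protein is pulled down with an antibody and the attached RNA fragments are sequenced. All 3 libraries formed 1 group, and no control or treated group was compared. The values were 4 peak lists made by 4 peak callers, CIMS, Piranha, Pyicoclip and PIPE-CLIP, each covering the series as a whole. No value per library was used, so the depth of each library is unknown and no spread between libraries could be given. The comparisons were therefore between the peak lists, which come from the same cells and are not replicates of each other. All positions are in mm10, counted from 1.

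CIMS held 169 peaks of 41 nt each, and Piranha held 1417 peaks with a median width of 20 nt. Pyicoclip held 2068 peaks with a median width of 29 nt, and 52.0% of them were at most 30 nt wide. PIPE-CLIP held 3257 clusters with a median width of 85 nt and a minimum of 30 nt. The lists covered 6914, 33880, 149510 and 321980 nt in that order. The lowest score was 10 in each list. Peaks were spread evenly over both strands in Piranha, with 50.3% on the minus strand (95% Wilson interval 47.7 to 52.9), and in Pyicoclip, with 48.5% of stranded peaks (46.3 to 50.7). CIMS had 39.1% on the minus strand (32.0 to 46.6). PIPE-CLIP had 2835 minus-strand and 422 plus-strand clusters, a minus-strand share of 87.0% (85.9 to 88.2).

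The first comparison asked which bound sites the 4 callers found in common. A shared site here is a merged locus with peaks of all 4 lists, which need not all overlap each other. Peg10, an imprinted gene derived from a retrotransposon, held the most peaks among genes present in all 4 lists, with 3 from CIMS, 8 from Piranha, 8 from Pyicoclip and 15 from PIPE-CLIP. Its shared site lay at chromosome 6, 4759308 to 4760219, within the gene span of 4747306 to 4760517, and the Pyicoclip peak there scored 74. Lin28a, an RNA-binding protein of pluripotent cells that blocks the maturation of let-7, had a shared site at chromosome 4, 134004123 to 134004705. Slc2a3, a glucose transporter gene, was shared at chromosome 6, 122728775 to 122729249. Gigyf1 was shared at chromosome 5, 137526740 to 137526999, and Ccng2, the gene of cyclin G2, at chromosome 5, 93270805 to 93271046. At the sites of Lin28a, Slc2a3 and Ccng2, the CIMS and Piranha peaks did not overlap each other and were joined by a wider Pyicoclip peak.

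Merging overlapping peaks over all lists, with strand ignored, gave 4617 loci. Of these, 40 held peaks of all 4 lists, 245 of 3 lists, 1425 of 2 lists and 2907 of 1 list. The 40 loci included sites in Malat1, a nuclear long non-coding RNA, in Slc38a2, an amino acid transporter gene, and in Bsg, Arhgap21, Peak1 and Stard9. The small nuclear RNA gene Rn7sk and the U3 small nucleolar RNA gene Rnu3a were among them, as were 2 loci at the ribosomal RNA locus Rn18s-rs5 on chromosome 17. A further 14 lay in no annotated gene. Jarid2, a partner of Polycomb repressive complex 2, had a shared site at chromosome 13, 44869768 to 44870046, on the minus strand. Other Jarid2 peaks, at 44919906 to 44920107 in Pyicoclip and 44920001 to 44920020 in Piranha, were on the plus strand, so peaks of this gene span came from both strands. The strand of the gene was not used, so it is uncertain whether the shared site comes from the Jarid2 transcript.

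Each of the 6 pairs of lists overlapped more than after random local shifts of the shorter list. Of the Piranha peaks, 95.7% (94.5 to 96.6) overlapped a Pyicoclip peak, against a mean of 1.33% after shifts. CIMS peaks overlapped Pyicoclip in 75.7% (68.8 to 81.6) against 8.03%, PIPE-CLIP in 74.6% (67.5 to 80.5) against 28.4%, and Piranha in 65.1% (57.6 to 71.9) against 13.5%. PIPE-CLIP overlapped 30.7% of the Pyicoclip peaks (28.7 to 32.7) against 3.16%, and 23.5% of the Piranha peaks (21.4 to 25.8) against 4.64%. The one-sided permutation p, adjusted by Benjamini-Hochberg over the 6 pairs, was 0.000999 for each, the smallest that 1000 shifts can give. All lists were made from the same libraries, so an overlap above the shifts was all but certain beforehand. The test therefore does not show that the sites are reproducible, and only the sizes of the shares are informative. Without the mitochondrial chromosome and the Rn18s-rs5 locus, 113 of 113 CIMS peaks overlapped Pyicoclip, since the Pyicoclip list held no mitochondrial peak, while 62.0% overlapped PIPE-CLIP and 56.6% Piranha. Where at least 50% of the peak had to overlap, CIMS in Piranha fell to 32.0% (25.4 to 39.3), a setting in which a single 20-nt Piranha peak cannot cover enough of a 41-nt CIMS peak.

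**Figure D1:**
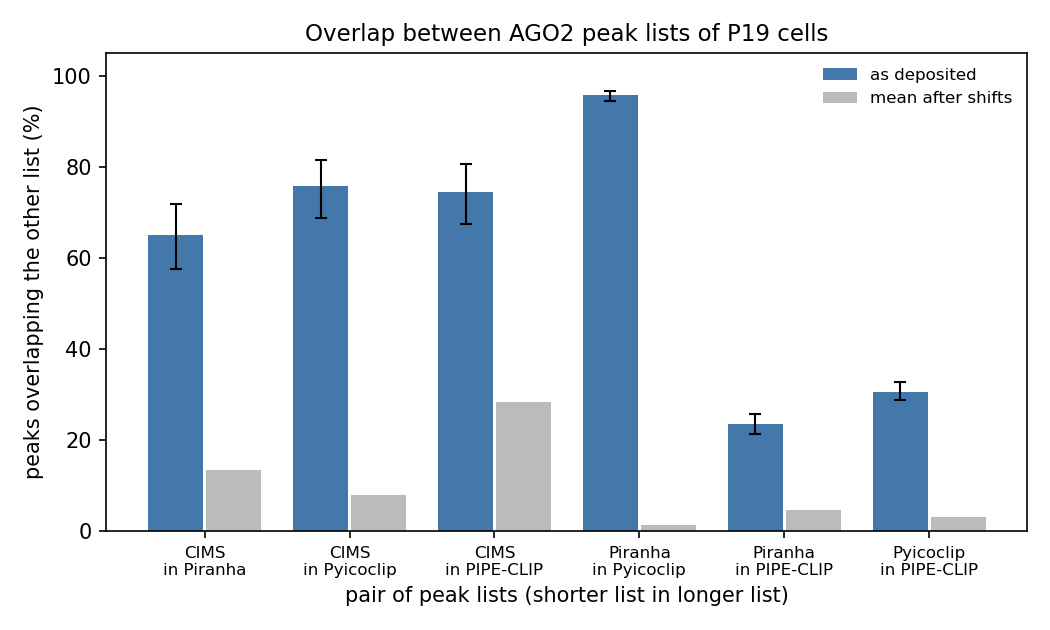
Share of the peaks of the shorter list that overlapped a peak of the longer list, in percent, for the 6 pairs of lists. Blue bars are the lists as deposited with 95% Wilson intervals, grey bars the mean after 1000 random shifts; Piranha in Pyicoclip is highest at 95.7% and Piranha in PIPE-CLIP lowest at 23.5%.

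Read from the longer list, the overlap was uneven. All 169 CIMS peaks, 1416 of 1417 Piranha peaks and 83.3% of Pyicoclip peaks overlapped at least 1 other list, against 20.8% of PIPE-CLIP clusters (19.5 to 22.3). Among PIPE-CLIP clusters the share was 78.4% on the plus strand (74.3 to 82.1) and 12.2% on the minus strand (11.1 to 13.5). Clusters of PIPE-CLIP alone made up 2563 of the 2907 loci in 1 list.

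**Figure D2:**
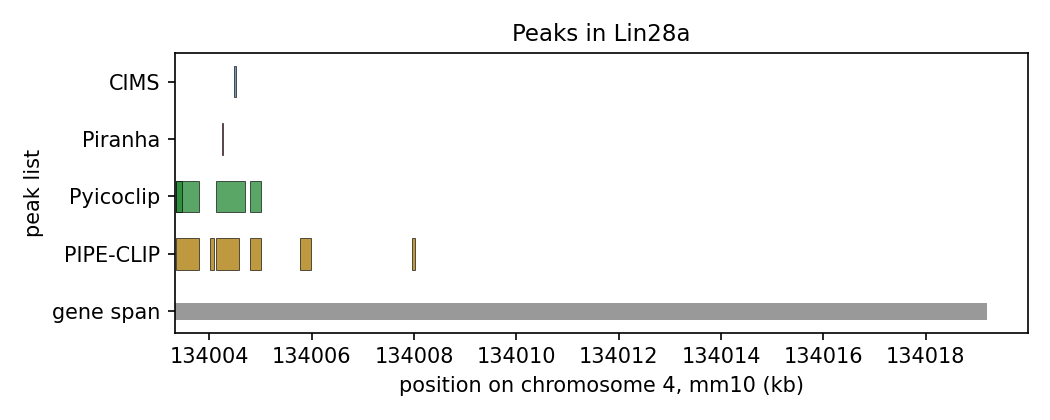
Peaks of the 4 lists along the Lin28a gene span on chromosome 4 of mm10, in kb. Boxes are single peaks, overlapping boxes are darker, and the grey bar is the gene span of 134003330 to 134019196; the peaks of CIMS, Piranha and Pyicoclip lie towards the low-coordinate end, and PIPE-CLIP has 6 clusters reaching to 134008022.

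The second comparison was of the RNA classes under the peaks. Protein-coding gene spans, such as those of Peg10 and Lin28a, held 88.5% of PIPE-CLIP clusters (87.3 to 89.5), 59.0% of Pyicoclip peaks (56.9 to 61.1), 47.4% of Piranha peaks (44.8 to 50.0) and 34.3% of CIMS peaks (27.6 to 41.8). Mitochondrial RNAs held 24.3% of CIMS peaks (18.4 to 31.3), 3.81% of Piranha peaks and 1.23% of PIPE-CLIP clusters, and 0 of 2068 Pyicoclip peaks, which allows a share of up to 0.145% by the limit of 3 counts of the total. The span of the mitochondrial gene ND5, which encodes a subunit of respiratory complex I, held 14 CIMS peaks and 15 Piranha peaks. All 14 and 14 of the 15 were on the minus strand, opposite to the known direction of ND5, and PIPE-CLIP had 7 plus-strand clusters and 1 minus-strand cluster there. The span of mt-Rnr2, the large mitochondrial ribosomal RNA, carried 10 and 11. Ribosomal RNA, with the Rn18s-rs5 locus counted in, held 10.1% of CIMS peaks (6.38 to 15.5), 1.34% of Piranha peaks, 0.532% of Pyicoclip peaks and 0.276% of PIPE-CLIP clusters. MicroRNA genes held 2.68% of Piranha peaks (1.96 to 3.66), 2.66% of Pyicoclip peaks (2.05 to 3.45), 1.18% of CIMS peaks (0.325 to 4.21) and 0.246% of PIPE-CLIP clusters (0.125 to 0.484).

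**Figure D3:**
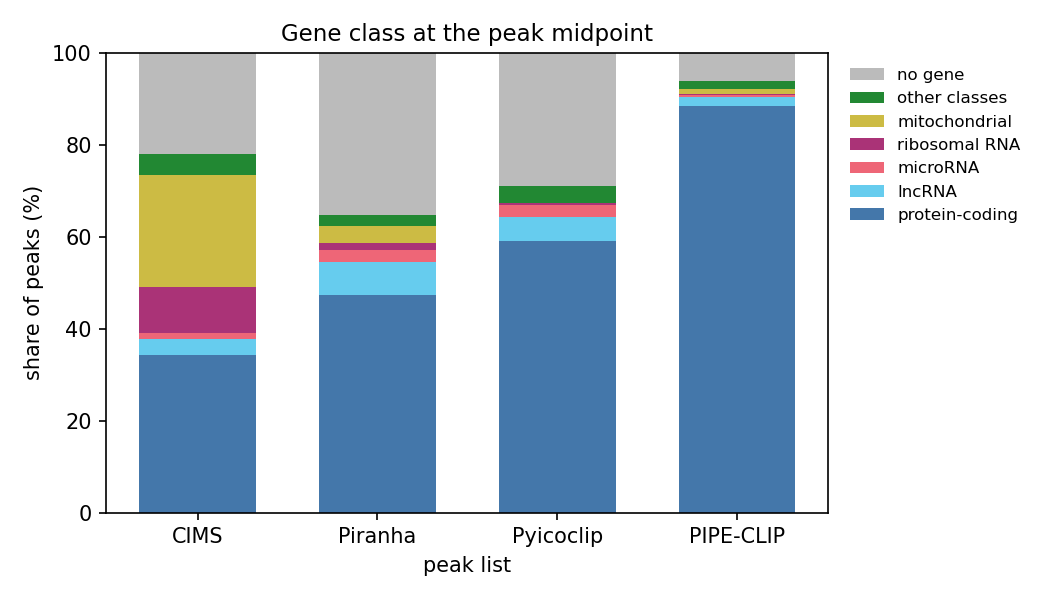
Share of peaks per list, in percent, by the annotated gene class at the peak midpoint. Stacked bars add to all peaks of a list; protein-coding spans rise from 34.3% in CIMS to 88.5% in PIPE-CLIP, and mitochondrial RNAs stand out in CIMS at 24.3%.

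By Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 18 tests of 3 classes, the microRNA share was higher in Pyicoclip than in PIPE-CLIP (adjusted p = 3.79e-15) and in Piranha than in PIPE-CLIP (adjusted p = 5.40e-13). The difference from Pyicoclip was clear only in peaks of at most 60 nt. Over 60 nt, Pyicoclip had 0.515% (0.200 to 1.32) and PIPE-CLIP 0.184% (0.0786 to 0.430), with overlapping intervals, and widths were not matched in the tests. The microRNA share did not differ detectably between Piranha and Pyicoclip (exact test, adjusted p = 1.0), nor between CIMS and any other list (adjusted p = 0.101 against PIPE-CLIP). Peaks in no annotated gene made up 35.2% of Piranha, 28.9% of Pyicoclip, 21.9% of CIMS and 6.05% of PIPE-CLIP, and 5 of the 6 pairs differed. CIMS against Pyicoclip was the exception (exact test, adjusted p = 0.0796). The tests and intervals count each peak as independent, although a list can hold several peaks of 1 RNA. Examples are 3 nested Pyicoclip peaks at Mir6236 and 15 CIMS peaks in the Rn18s-rs5 span. The p-values may thus be too small and the intervals too narrow. The lists share sites, so the tests were also run on peaks that were not shared by the pair compared. The microRNA calls were the same there, with 3.28% of Pyicoclip against 0.0768% of PIPE-CLIP (exact test, adjusted p = 8.40e-19). For peaks in no gene, CIMS and Piranha cannot be compared with Pyicoclip in this way, since all unshared CIMS and 88.5% of unshared Piranha peaks were mitochondrial. For mitochondrial RNAs, CIMS had 0 against 0.943% in PIPE-CLIP (exact test, adjusted p = 1.0) and Piranha 0 against 0.80% (exact test, adjusted p = 0.00134), so the higher shares of CIMS and Piranha lay in peaks shared with PIPE-CLIP.

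Ribosomal or mitochondrial RNAs were among the 5 highest-scoring peaks of each list. Rn18s-rs5 gave 3 of the 5 highest CIMS scores and the 2 highest Pyicoclip scores, of 229 and 215. The 5S ribosomal RNA gene n-R5s109 on chromosome 8 gave the highest Piranha score of 87 at 123554061 to 123554080 and another of 60. The other 3 Piranha peaks were in the long non-coding RNA gene Gm15564, with a score of 72, and in no gene, with 63 and 62. A cluster of 2474 nt on the mitochondrial minus strand, 11598 to 14071, gave the highest PIPE-CLIP score of 1542. Its midpoint lay in ND5, but it also covered the span of ND6, 13552 to 14070, so its gene of origin is uncertain. The spans of mt-Rnr2 and mt-Rnr1 gave clusters of 635 and 513. Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, had a Pyicoclip peak of 177 at chromosome 9, 123461884 to 123462189. A site in no annotated gene at chromosome 3, 5860337 to 5860827, scored 189 in Pyicoclip, and the CIMS peak inside it had the highest CIMS score of 187. Ribosomal RNA genes have near-identical copies, so the copy of origin is uncertain for Rn18s-rs5 and n-R5s109.

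The third comparison was of where peaks lay along protein-coding genes. Lefty1, a secreted inhibitor of Nodal signalling with a span of 180935022 to 180938401 on chromosome 1, had a CIMS peak scoring 53 at 180938130 to 180938170. Its PIPE-CLIP cluster at 180937979 to 180938391 scored 110. Cdkn1b, the gene of the cell cycle inhibitor p27, has a span of 134920401 to 134925525 on chromosome 6. It had peaks of Piranha, Pyicoclip and PIPE-CLIP between 134924288 and 134925445.

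Counting the highest-scoring peak of each gene, the last 10% of the span held 47.8% of 46 genes in CIMS (34.1 to 61.9), 43.2% of 1409 genes in PIPE-CLIP (40.7 to 45.8), 32.9% of 821 genes in Pyicoclip (29.8 to 36.2) and 21.1% of 555 genes in Piranha (17.9 to 24.7). The first 10% held 2.17%, 8.87%, 11.8% and 12.8% of genes in the same order. The last part exceeded the first by an exact binomial test, two-sided, in each list, with p = 5.72e-06, 3.25e-77, 5.43e-20 and 0.000979, unadjusted over 4 tests. Between lists, Fisher's exact test with adjustment over 6 pairs gave a higher share in PIPE-CLIP than in Pyicoclip (adjusted p = 3.51e-06), and a lower share in Piranha than in each other list (largest adjusted p = 0.000245). CIMS did not differ detectably from Pyicoclip (exact test, adjusted p = 0.0636) or from PIPE-CLIP (adjusted p = 0.549). These tests treat the lists as independent although they share sites, and they were not repeated on unshared peaks. In Pyicoclip the share was 59.4% for peaks over 30 nt (54.3 to 64.3) and 12.7% for peaks of at most 30 nt, where the ends did not differ detectably by the exact test (p = 0.148). For these narrow peaks the first 10% of the span held more genes than the last, with 16.6%. Over 30 nt the order of Pyicoclip and PIPE-CLIP was thus reversed, since PIPE-CLIP had 43.3% there (40.7 to 45.9). The lower share of Piranha than of Pyicoclip also depended on width. Among peaks of at most 30 nt, Piranha had the higher share, with 21.28% of 545 genes (18.06 to 24.92). Pyicoclip had 12.74% of 471 genes there (10.03 to 16.05). Over 30 nt Piranha was lower, with 20.83% of 24 genes. Differences between lists at like widths were not tested. Within PIPE-CLIP the share was 63.6% of 154 genes on the plus strand (55.8 to 70.8) and 40.7% of 1255 genes on the minus strand. In Piranha the ends did not differ detectably for minus-strand peaks, with 17.5% in the last part of the span (exact p = 0.161), or for peaks over 30 nt (24 genes, exact p = 0.219).

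**Figure D4:**
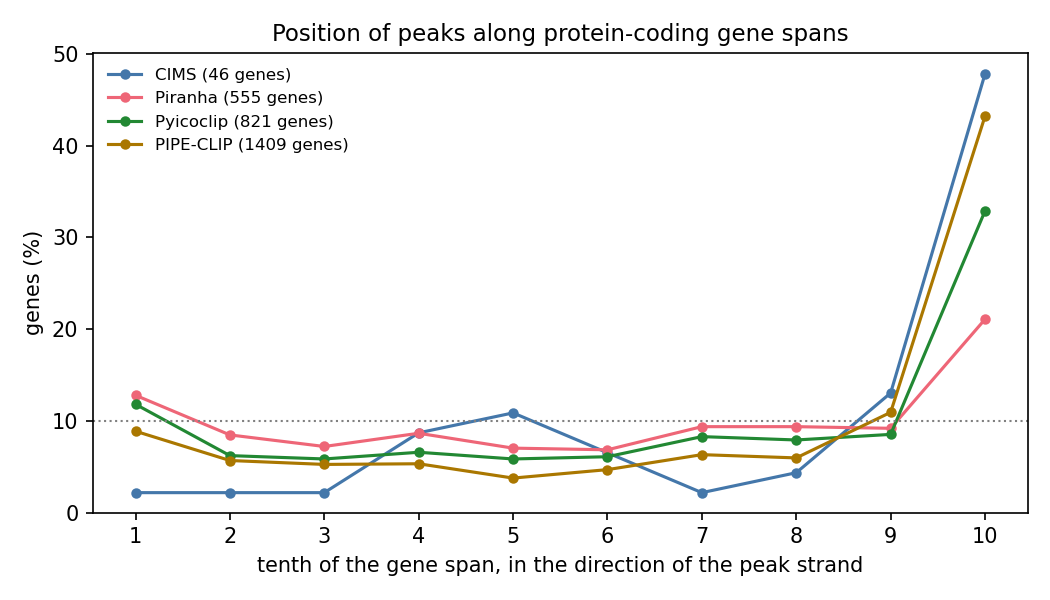
Position of the highest-scoring peak of each protein-coding gene, as the percentage of genes in each of 10 equal parts of the gene span, read in the direction of the peak strand. Each line is 1 peak list and the dotted line marks an even spread of 10%; the last part reaches 47.8% in CIMS, 43.2% in PIPE-CLIP, 32.9% in Pyicoclip and 21.1% in Piranha.

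The fourth comparison asked whether peaks found by another caller scored higher within their own list. The PIPE-CLIP clusters at the shared sites of Peg10 and Lin28a scored 231 and 144, against a list median of 14. That of the minus-strand site in the Jarid2 span, of uncertain origin, scored 100. The clusters at the shared sites of Slc38a2, Gigyf1, Ccng2 and Malat1 scored lower, at 25, 24, 16 and 15. The median PIPE-CLIP score was 19 for 678 clusters that overlapped another list and 13 for 2579 that overlapped none, and the mean score percentile was higher by 22.8 points. In Pyicoclip the medians were 13 for 1723 peaks and 11 for 345 peaks, with a difference of 20.4 points. Both differences had p = 1e-05 by two-sided permutation tests, the smallest that 100000 resamples can give. The lists were made from the same libraries, and none held a score below 10. If scores follow read numbers, a peak near that floor misses the other lists more easily. A difference in this direction was thus likely beforehand and is not separate evidence of binding. CIMS and Piranha had 0 and 1 peaks outside other lists and were not tested.

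The fifth comparison was of the genes that held peaks. In total, 2583 genes had a peak in at least 1 list, among them 2140 protein-coding genes, 9.77% of those annotated. Genes with peaks in all 4 lists numbered 33, with 237 in 3 lists, 880 in 2 lists and 1433 in 1 list. PIPE-CLIP was the only list for 1258 genes. Among the 33, Peg10 had 34 peaks, Rn18s-rs5 and Slc2a3 had 30 each, Gigyf1 had 22 and Malat1 had 19. Here and below, peak counts of a gene are sums over the 4 lists. A site found by several callers counts several times, and so do overlapping intervals within a list, so the counts are not numbers of sites. Zbtb7a, Ccng2, Slc38a2, Lin28a, Trpm3, Gm36876, Lars2, Spata5, Cmss1, Filip1l, Gm19951 and Jarid2 had 8 to 17 peaks each. Cmss1 and Filip1l overlap in the genome and shared all 8 peaks, so the gene of origin is uncertain.

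Of the gene lists fixed in advance, chromatin regulators had 17 of 27 members with a peak, against a mean of 4.37 in random protein-coding lists matched on span length. Jarid2 was among them, with peaks on both strands. Others were the histone demethylase genes Kdm6b and Kdm2a, with 10 and 11 peaks, Suz12, Cbx7, Tet3, Chd1, Dnmt3a and Hdac2. Of the peaks of Kdm6b and Kdm2a, 8 and 10 were PIPE-CLIP clusters. Translation and ribosome genes had 13 of 24 members against 1.17, among them Eif3a with 16 peaks, Eef2 with 12, Npm1 with 10 and Pabpc1 with 7. Cell cycle regulators had 12 of 28 against 2.87, with Cdkn1b, Lats1, Btg1, E2f3, Cdk1 and Wee1 in at least 2 lists. Without PIPE-CLIP, 10 chromatin regulators against 2.11 and 6 cell cycle regulators against 1.25 had a peak (permutation, adjusted p = 0.00065 and 0.00631). Nuclear long non-coding RNAs had 7 of 14 against 0.336 in random lists of long non-coding RNA genes, with Malat1, Snhg1, Snhg12, Gas5, Mir17hg and Mirg in at least 2 lists. The peaks of Mir17hg and Mirg lay in the microRNA genes Mir92-1 and Mir541, and those of Gas5 and most of those of Snhg1 and Snhg12 lay in small nucleolar RNA genes inside the spans. Without peaks in small RNA genes, 4 of 14 remained (permutation, adjusted p = 0.00195). Snhg1 and Snhg12 stayed only through a 20-nt Piranha peak each. Both overlapped a Pyicoclip peak with its midpoint in a small nucleolar RNA gene, so this setting does not fully remove such peaks. These 4 lists had p = 0.0002 by two-sided permutation, the smallest that 10000 random lists can give, and adjusted p = 0.00065 over the 13 lists.

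Pluripotency genes had 9 of 30 members with a peak against 2.63 (permutation, adjusted p = 0.0026). Lin28a had 12 peaks, Trim71, a let-7 target and RNA-binding ubiquitin ligase, had 11, Otx2 had 5 and Mycn had 3. Klf4 and Klf5 had 2 each, which were overlapping peaks of Piranha and Pyicoclip. Among the genes of RNA silencing, 9 of 25 had a peak against 3.77 (permutation, adjusted p = 0.0225). Ago2 itself had 14 peaks, 12 of them from PIPE-CLIP, and the deadenylase gene Cnot6 had 16, 14 of them from PIPE-CLIP. Tnrc6a, Tnrc6b and Tnrc6c, which encode the Argonaute partners of the GW182 family, had 12, 7 and 4 peaks, Ago1 had 8 and Ago4 had 2. Cytoskeleton and housekeeping genes had 6 of 20 against 1.09 (permutation, adjusted p = 0.0052), with Hsp90ab1 at 12 peaks, Actb, Tubb5 and Pfn1 at 6 each and Pkm at 3. PIPE-CLIP gave 11 of the 12 peaks of Hsp90ab1. Of the 6 of Pfn1, 3 were on the plus strand and also in the span of Eno3, opposite to the strand of the others, so their gene of origin is uncertain.

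TGF-beta and BMP genes had 9 of 22 members with a peak against 3.57 (permutation, adjusted p = 0.0141), led by Skil with 10 peaks, Lefty1 with 7 and Tgfbr2 with 6. Neural differentiation genes had 8 of 26 against 3.04 (permutation, adjusted p = 0.0192), with Ncam1 at 6 peaks, Dll1 at 3, and Hes1 and Cdh2 at 2 each. Neither list passed without PIPE-CLIP, with 4 members against 1.78 (permutation, adjusted p = 0.309) and 2 against 1.66 (permutation, adjusted p = 1.0). Wnt genes had 7 of 22 against 3.04 (permutation, adjusted p = 0.0554), among them Tcf7l1, Lef1, Lrp5 and Fzd3. All peaks of Tgfbr2, Dll1, Cdh2, Tcf7l1 and Fzd3 were PIPE-CLIP clusters. Mesoderm and endoderm genes had 1 of 21, Lefty1 (permutation, adjusted p = 1.0), retinoic acid genes had 1 of 18, Nr6a1 (permutation, adjusted p = 0.774), and fibroblast markers had 0 of 12 against 1.31 (permutation, adjusted p = 0.580). Expression in P19 cells was not measured here, so the random lists include genes that may not be transcribed, and a gene without a peak is not shown to be unbound. Nr6a1 had 11 peaks, 6 of which lay in the microRNA genes Mir181a-2 and Mir181b-2 inside its span.

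The last comparison was of microRNA genes, where reads can come from the microRNA that AGO2 carries. Peaks lay in 52 annotated microRNA genes, 50 of them in Pyicoclip, 37 in Piranha, 8 in PIPE-CLIP and 2 in CIMS, and 37 were in at least 2 lists. Some are numbered copies, as Mir181a-1 and Mir181a-2, Mir92-1 and Mir92-2, or Mirlet7c-1 and Mirlet7c-2. How reads were assigned between copies is not known here, so the copy of origin is uncertain. A single Pyicoclip peak counted for both Mir292 and Mir292b. The gene counts are therefore not numbers of separate sources. Mir181a-1, at chromosome 1, 137966455 to 137966541, had peaks of Piranha, Pyicoclip and PIPE-CLIP, and its Pyicoclip peak scored 30. Mir182 on chromosome 6, Mir93 on chromosome 5 and Mir181b-2 on chromosome 2 were in the same 3 lists. Mir92-2, of a cluster on chromosome X at 52741838 to 52741928, had peaks of CIMS, Piranha and Pyicoclip that each scored 16. Mir302a, of a cluster typical of pluripotent cells, had 1 Piranha and 2 Pyicoclip peaks at chromosome 3, 127545496 to 127545564, and Mir92b had 2 of each. Mir6240 was in all 4 lists and Mir6236 in 3, with Pyicoclip scores of 26 and 151. Their Pyicoclip peaks were wide, at 84 nt for Mir6240 and 102 to 127 nt for 3 nested peaks of Mir6236. That of Mir181a-1 was 36 nt wide. It is therefore uncertain whether the reads of Mir6240 and Mir6236 come from a microRNA carried by AGO2.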

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

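The settings without PIPE-CLIP, without mitochondrial and ribosomal peaks or without small RNA genes, those on random positions in gene spans, plus-strand clusters, unshared peaks or single gene spans, all those on position, and the comparison among genes with a peak were chosen after the data were seen. All 45 alternative values of the overlap between lists and all 6 of the score of shared peaks kept their direction and side of the threshold, as did 17 of 19 for position. For overlap and score this was likely beforehand, since the lists were made from the same libraries. The call was the same for 14 of 18 RNA class differences and 49 of 64 gene list values, where differences that did not pass, such as mesoderm and endoderm, retinoic acid and Wnt genes, lay on either side of chance. The 23 untested RNA class shares stayed within their intervals when any overlap counted. The random mean of the overlap rose with positions inside the gene span, from 13.5% to 29.4% for CIMS in Piranha and from 28.4% to 45.7% for CIMS in PIPE-CLIP. On peaks that a pair did not share, the differences were -28.72 percentage points for no gene in CIMS minus Pyicoclip, now past the threshold, and reversed to -12.48 for no gene in Piranha minus Pyicoclip, -0.9425 for mitochondrial RNA in CIMS minus PIPE-CLIP and -0.7995 in Piranha minus PIPE-CLIP; against Pyicoclip the outcome was fixed, since all unshared CIMS peaks and 88.5% of unshared Piranha peaks were mitochondrial and Pyicoclip held none. The exceptions for position were Piranha peaks over 30 nt, with 20.83% in the last 10% of the span, and Piranha minus-strand peaks, with 17.48%. The first had only 24 genes, and the cause of the second was not tested. Peaks of at most 30 nt were not among the 19 values. For these, Pyicoclip was reversed, with 60 of 471 genes in the last 10% and 78 in the first (exact binomial test, p = 0.1476). Piranha kept its direction there, with 116 and 72. The better-scoring part of each list held 84, 708, 1034 and 1628 peaks by construction. Without PIPE-CLIP, 439 genes were in 1 list and 52 in 3 lists, since fewer lists were counted. Neural genes fell to 2 and TGF-beta and BMP genes to 3 members with a peak in at least 2 lists, and to 2 and 4 without PIPE-CLIP. Wnt genes, with 7 members, passed the threshold against unmatched random lists (permutation, adjusted p = 0.0118) and without small RNA genes (permutation, adjusted p = 0.0494). Among genes with a peak, no list differed from chance in its members in at least 2 lists (adjusted p from 0.354 to 0.912): 6 pluripotency, 7 RNA silencing, 6 cell cycle, 10 chromatin, 9 translation, 5 housekeeping and 6 long non-coding RNA genes. Neural genes with 2, TGF-beta and BMP genes with 3 and Wnt genes with 2 lay below the random mean there. These sets are small, and the cause was not tested. Not run were random positions in exons, sense exonic peaks alone, and all alternatives for 3′ untranslated regions and seed matches, which need exons or sequence, and leaving out each library, since the lists join all 3. No paired analysis was possible because the design has 1 group.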

Other observations

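The tests of strand by gene end and by other lists, of recovery at Pyicoclip sites, of narrow peaks, and of chromosome copies were chosen only after the result was seen. Further microRNA genes had peaks of both Piranha and Pyicoclip. Mir302b and Mir302d, of the same cluster as Mir302a, had Pyicoclip scores of 13 and 12, and Mir293, of a cluster of early embryonic microRNAs on chromosome 7, had a score of 10. Mir25 had a score of 15 in the cluster it shares with Mir93, and Mir183 had 24 in the cluster it shares with Mir182. Mirlet7c-1, Mirlet7c-2 and Mirlet7e, members of the let-7 family that Lin28a acts on, had Pyicoclip scores of 12, 11 and 11. For Mirlet7c-1 and Mirlet7c-2 the copy of origin is uncertain. Igf2bp1, an RNA-binding protein gene on chromosome 11, had 5 Pyicoclip peaks and 16 PIPE-CLIP clusters, and Pou5f1, the gene of the pluripotency factor OCT4, had 1 PIPE-CLIP cluster.

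PIPE-CLIP clusters lay mostly on the minus strand, against at most 50.25% of peaks in the other 3 lists, which argues against binding mostly on the minus strand as a biological explanation. Of the minus-strand clusters in the first or last 10% of a gene span, 19.15% (16.3 to 22.4) lay at the high-coordinate end, where plus-strand genes end. This argues against a full mix, in which clusters of both strands were all written as minus. Read in the direction of the strand, the last part held 80.85% of minus-strand and 96.08% of plus-strand clusters at either end. Some clusters written on the wrong strand are therefore not excluded, and this was not tested. A loss of low-scoring plus-strand clusters stays open: the minus-strand share fell from 88.8% in the lower-scoring part of the list to 75.08% (70.1 to 79.5) in the highest-scoring 10%, which is neither near the 50% that such a loss predicted nor clearly above the 75% set in advance against it, while that part of Piranha had 63.1% (54.9 to 70.6). At Pyicoclip peaks over 60 nt with lower scores, a PIPE-CLIP cluster was present at 54.03% (47.3 to 60.6) on the plus strand and 77.3% (70.5 to 82.8) on the minus strand, so plus-strand sites may be missing in part, though the share was above 50% of that on the minus strand, and at higher scores the shares were 88.7% and 89.2%. Extra minus-strand clusters were not tested and also stay open: 12.2% of minus-strand against 78.4% of plus-strand clusters were in another list.

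Pyicoclip peaks of at most 30 nt lay in gene spans in 63.01% (60.1 to 65.8), less often than peaks over 60 nt with 83.9% (81.2 to 86.3), and 85.7% of them overlapped Piranha and 0.0929% PIPE-CLIP, whose clusters are at least 30 nt wide. A scatter over the genome without regard to genes would give 45.8%, so it is argued against as the source of all narrow peaks, although the last 10% of protein-coding spans held 12.7%, near an even spread. Reads of annotated microRNA genes do not make up the class, since 3.439% (2.51 to 4.70) lay in such genes. What the remaining narrow peaks are stays open, and no biological explanation was tested.

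Chromosome 11 held 13.0% of nuclear PIPE-CLIP clusters (11.9 to 14.2), against 7.35% of protein-coding genes. Extra copies of the chromosome are argued against, since Pyicoclip had 7.882% there (6.80 to 9.12). The excess was in minus-strand clusters with 13.9% (12.6 to 15.2), and minus-strand Pyicoclip peaks had 9.30% (7.60 to 11.3) against 6.33% on the plus strand, while PIPE-CLIP plus-strand clusters had 7.125% (4.98 to 10.1), so a candidate explanation is that it comes with the strand imbalance of the list. Chromosome 15 had a like excess, with 194 of 3217 clusters against 776 of 21887 genes, so the pattern is not particular to chromosome 11, and why clusters concentrate there stays open.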
